A study of Bacillus subtilis with 111 samples.

How the data were processed

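RNA of *Bacillus subtilis* 168 and BSM29 from the same condition and time was hybridised together on arrays that target the SigB regulon. Per the labels, cells were precultured in LB and grown in a defined minimal medium, RNA was taken with acid phenol after mechanical disruption, and cDNA was primed with random hexamers and labelled with Cy3 or Cy5. The 111 arrays comprise 79 with BSM29 in Cy3 and 32 with swapped dyes. The deposited files per array give scanner signals (signal intensity in fluorescence units, with the local background already subtracted) and a flag for each of 3 spots per gene. A deposited value table gives a ratio of wild type over BSM29 per gene and array; the authors' normalization of this ratio is not stated in the labels. Its log2 followed the spot signals above the floor on every array (correlation across genes 0.889 to 1.00), with column medians from 0.524 to 3.50, so that it is not centred, and it serves only as an alternative here. Gene symbols are printed as the files give them, and 262 of the 350 match a symbol of the reference annotation.

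Signals were raised to a floor of 50 units. Spots flagged A in both channels were left out where another spot of the gene was not. Of the readings, 1 per spot and channel, 6.59% lay below the floor, 13.1% carried the flag and 0.693% were above the saturation limit of 65000 units. On each array, log2 of wild type over BSM29 was corrected by a loess curve against signal (span 0.4, 4 iterations) fitted on the spots of the 248 genes outside the SigB lists, and the spots of a gene were averaged. The median standard deviation among spots of a gene was 0.08 log2. A gene-specific dye effect, from the 32 pairings of swapped with other arrays, was subtracted from the arrays with BSM29 in Cy3 (median size 0.10 log2, 90% of genes below 0.27, largest 0.56). The labels count 2 biological replicates per time, so the swapped array repeats 1 of them without saying which; by correlation 14 were closer to replicate 1 and 18 to replicate 2. Swapped arrays therefore entered the dye correction alone. No array was identical to another (0 found).

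The times of a replicate were averaged, since they may come from 1 culture, into 34 values for stress, phase and replicate. A limma fit (version 3.58.1, R 4.3.3) over all groups gave each comparison, with 20 residual and 5.49 prior degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over 350 genes. After a stress and at OD 1.0, both replicates also had to lie on the same side of 0. For changes from 0 min this held for the changes of both replicates. No side rule applied before stress, at OD 0.9 or in contrasts between stresses. Adjusted p values in the text come from these limma fits. The comparisons were the difference after each stress, at 15 °C (OD 0.9 and OD 1.0), before stress over the 6 series, and the change from 0 min, then single times, an F-test and pairwise contrasts over the 6 stresses. Butanol, with 1 array per time, was given as values. Induction within a strain used the mean log2 signal plus or minus 0.5 of the log2 ratio, centred on the genes outside the SigB lists.

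Gene lists, comparisons and the rule for named genes were fixed before the data were examined. The lists cover the sigB operon, the core SigB regulon, heat-shock genes of CtsR and HrcA, peroxide and thiol stress, osmoprotectant uptake, cold shock, oxygen and nitrate, carbon starvation, envelope stress and housekeeping. The SigB lists hold 102 measured genes, and the array itself was chosen for this regulon. Lists with 3 or more measured genes (7 lists, 105 tests) were tested with fry and with camera, each adjusted over all these tests. The fry test asks whether a list's genes move on balance one way. The camera test, with an estimated correlation between genes, asks whether they move more than the other genes on the array. A list p given with an estimated correlation is that of camera, and any other list p is that of fry. The 2 tests put different questions and can point opposite ways. The operon and core lists share 4 genes, and opuE and yceD each stand on 2 lists. Named were the 10 highest and 5 lowest called genes per comparison, the 25 highest over the stresses, up to 3 genes per stress called in it alone, up to 4 members per list, the 10 largest rises in BSM29 and a fixed set (sigB, rsbV, rsbW, rsbX, gsiB, ctc, katE, gspA, yvyD, dps, clpC, clpP, trxA, opuE, yqgZ). Genes named outside that rule, among them lexA, purK, sat, nadC, bioB, mmgB and mmgD, were chosen after their values were seen, as were the comparisons of the last with an earlier time.

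Where BSM29 was not detected on any array of a comparison, or wild type was saturated on all of them, only a bound on the fold is given. Deviations between replicates 1 and 2 before and after stress correlated across genes at 0.24 (heat) to 0.44 (glucose) in the 6 series. The replicate numbers may thus pair the samples, though single times correlated as low as 0.04 and the labels name no cultures. The main fits of changes from 0 min and of induction, with their SE, do not use this pairing. Counts with replicate number as a block are given beside those they changed. On simulated data with 25 genes at each size, 16 to 24% of differences of 0.5 log2 were found after ethanol, heat and glucose. There 72 to 88% of differences of 1 log2 and 100% of those of 2 log2 were found, with 0 of 250 unchanged genes called. At 15 °C 80% of differences of 0.5 log2 were found, and 8 of 250 unchanged genes were called. The simulation drew noise separately for each array and changed as many genes outside the lists up as down. It therefore does not cover noise shared by the times of 1 culture, nor a shift caused by the centring, and real error rates may be higher.

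Alternatives were loess on all genes, median centring, no dye correction, 3 uses of the swapped arrays, the deposited ratios, each stress fitted alone, an intensity trend, dim genes left out, each replicate or series left out, the OD 1.0 arrays added to OD 0.9 and, for induction, quantile-normalised mean signals. After the data were seen, centring on the mode of the genes outside the lists, a floor of 25, an offset of 50, all spots kept and centred deposited ratios were added, the mode also after loess. The loess on all genes moved the median of all genes by up to -0.44 log2 over all comparisons, changes from 0 min included, the deposited ratios by -0.66 to 0.76, mode centring by -0.11 to 0.46, loess with mode centring by up to 0.40 and centred deposited ratios by up to 0.13. Gene positions were not used here.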

Results

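Wild-type *Bacillus subtilis* 168 and strain BSM29 were compared on 111 two-colour arrays of 350 genes. Each array carried cDNA of both strains from the same condition and time, 1 strain in Cy3 and the other in Cy5. The series title names the SigB regulon, the genes read by the general stress sigma factor of this bacterium; for BSM29 the labels give a spectinomycin preculture and no genotype. Ethanol (4% v/v), heat (37 to 48 °C), salt (4% w/v NaCl) and hydrogen peroxide (60 µM) were sampled at 0, 5, 10, 15 and 20 min, with 10 arrays and 5 with swapped dyes per series. Glucose limitation (0.05% w/v) and oxygen limitation (shaking lowered from 210 to 50 rpm) were sampled at 0, 15, 30, 45, 60 and 90 min, with 12 arrays and 6 with swapped dyes each. Growth at 15 °C gave 8 arrays at OD 0.9 and 2 at OD 1.0, and butanol (1% v/v) gave 5 arrays of 1 culture series. The median signal per array ran from 130 to 893 units for BSM29 and from 147 to 2496 for wild type, and 207 to 342 genes of BSM29 and 284 to 345 of wild type were detected per array. The number of arrays limits the precision. Values are log2 of wild type over BSM29, so that a positive value is higher in wild type, with the standard error (SE). Each value after a stress has n = 2 biological replicates, each a mean over the times after 0 min, unless another n is given. The SE pools the spread of a gene over all groups of the fit. A gene therefore has the same SE after each stress, however far apart its 2 replicates lie there.

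The 0 min samples ask what differed between the strains without stress. The gene for the sigma factor itself, sigB, was higher in wild type on 19 of 19 arrays before stress (log2 2.45 to 4.08), on 82 of 82 after stress (2.76 to 7.08) and on 10 of 10 at 15 °C (4.24 to 5.68). Over the 6 series at 0 min, sigB had a mean of 3.18 ± 0.11 (SE, n = 12) and rsbX, the feedback phosphatase encoded beside it, 3.47 ± 0.12. The anti-anti-sigma factor gene rsbV (0.36 ± 0.07) and the anti-sigma factor gene rsbW (0.34 ± 0.08) differed far less, and without the salt series their values of 0.22 and 0.20 were no longer called. Of other genes, gsiB (a hydrophilic general stress protein, 1.37 ± 0.20), yqgZ (the regulator MgsR of a part of the SigB regulon, 1.34 ± 0.10), manP (mannose uptake, 1.31 ± 0.10), mmgE (a methylcitrate dehydratase, 0.96 ± 0.11), yhdN (an aldo-keto reductase, 0.74 ± 0.07) and katE (a catalase, 0.69 ± 0.14) were higher in wild type. The esterase gene nap was the lowest called gene at -4.64 ± 0.16. In all, 34 genes were higher and 17 lower in wild type. A fit of these 12 arrays alone called 25 genes, and changing the signs of whole series called up to 24. The count before stress is therefore not set clearly apart from chance.

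Of the 5 measured genes of the sigB operon, 4 were higher before stress (4 adjusted over the list alone, list test adjusted p = 2.46e-15). The core SigB list had 18 of 101 genes higher and 1 lower (20 and 1 adjusted over the list alone, adjusted p = 0.00022; adjusted p = 0.369 with an estimated correlation), and its median of 0.05 turned to -0.27 with the deposited ratios and to -0.04 with centring on the mode. Among the osmoprotectant genes 0 were higher and 3 lower (1 and 3 adjusted over the list alone, adjusted p = 0.00618; adjusted p = 0.248 with an estimated correlation). The yce genes of the envelope list had 0 calls in limma (4 at an unadjusted p under 0.05), and 3 lower ones adjusted over the list alone (adjusted p = 0.0282; adjusted p = 0.391 with an estimated correlation). A few cultures carried some 0 min values. The ribosomal protein paralogue gene ytiA, which zinc represses, had a mean of 1.62 ± 0.46, and 0.91 without the ethanol series, where the call ended. Its 0 min values were 3.95 and 6.38 with ethanol, 6.38 in replicate 1 of glucose limitation and 3.88 in replicate 1 of salt, and ran from -0.55 to 0.22 in the other 8 cultures. The siderophore gene dhbA (-0.82 ± 0.18) and the siderophore uptake gene feuA (-0.48 ± 0.13) turned to 0.15 and 0.19 without the oxygen series. With the deposited ratios, 11 genes were higher and 152 lower before stress.

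**Figure D1:**
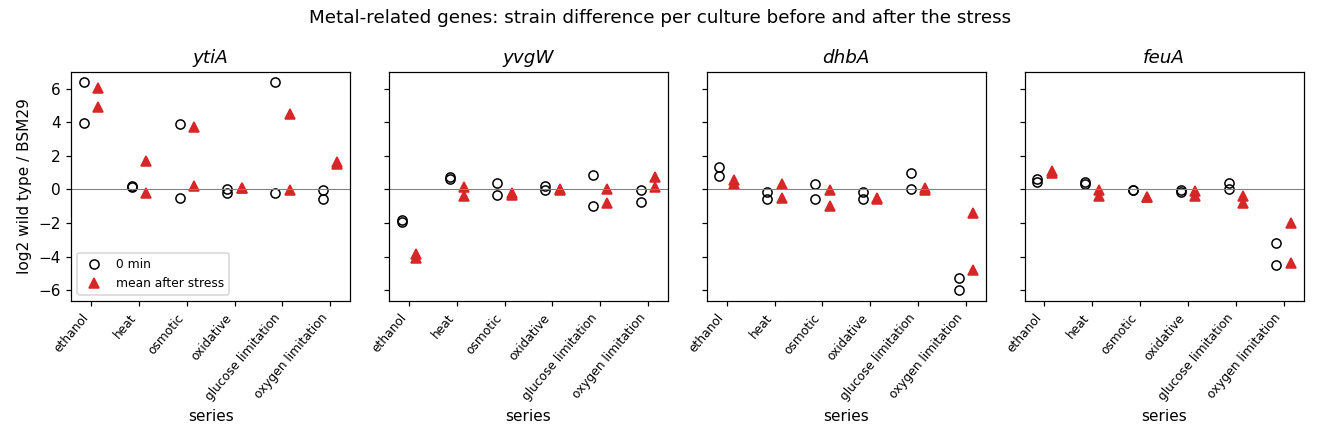
Log2 of wild type over BSM29 (vertical axis) at 0 min and after 0 min in each stress series, 1 point per biological replicate, for 4 genes. For ytiA both ethanol cultures (3.95 and 6.38) and 1 culture each of glucose limitation (6.38) and salt (3.88) lay apart at 0 min, while dhbA lay at -6.02 and -5.26 at 0 min of the oxygen series.

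The ethanol series asks which genes the wild type expressed more than BSM29 under this stress. The glycosyltransferase-like gene gspA reached 7.74 ± 0.40 (214-fold), the formate dehydrogenase-like gene yjgC 7.26 ± 0.26 and ykzA, which encodes a peroxidase for organic hydroperoxides, 6.96 ± 0.28. For genes whose wild-type signal was saturated on every array, gsiB was at least 427-fold higher (adjusted p = 6.14e-15), ydaS at least 184-fold (6.58e-17), mmgE at least 123-fold (7.23e-18) and yflT at least 99.7-fold (2.64e-18). Where BSM29 was not detected, yjgB was at least 89.9-fold higher (3.98e-18), yqhP at least 44.6-fold (4.02e-14), katE at least 40.1-fold (4.07e-14) and spoIIQ, known from forespore engulfment, at least 30.6-fold (5.85e-17). Within the sigB operon, sigB reached 5.32 ± 0.26, rsbX 4.99 ± 0.29, rsbV 3.47 ± 0.17 and rsbW 3.18 ± 0.19. Lower in wild type were nap (-4.40 ± 0.39), the metal efflux gene yvgW (-3.97 ± 0.34), yfmG (-2.11 ± 0.20), yazC (-1.88 ± 0.15) and yisP (-1.68 ± 0.20). Values at 0 min of the same series were 3.95 and 6.38 for ytiA and -1.95 and -1.80 for yvgW, beside 5.47 ± 1.13 and -3.97 after ethanol.

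By list, 76 of 101 core SigB genes were higher after ethanol and 6 lower (77 and 6 adjusted over the list alone, adjusted p = 7.02e-19), among the lower ones dps, a ferritin-like DNA-binding protein gene (-1.11 ± 0.19). All 6 measured yce genes of the envelope list were lower in wild type (6 adjusted over the list alone, adjusted p = 0.000136; adjusted p = 0.369 with an estimated correlation), such as yceC at -0.65 ± 0.17 and yceF at -0.84 ± 0.18. Under each of the 6 other scalings yceC, yceF, yceG and yceH stayed negative, and with the deposited ratios none of them was called. Without replicate 2, yceG (-0.65) and yceH (-0.64) were no longer called. Osmoprotectant genes split, with opuBD (4.92 ± 0.30) and the proline transporter gene opuE (3.45 ± 0.21) higher and 7 lower (2 and 7 adjusted over the list alone). Lower were opuBA (-1.65 ± 0.26) and opuAA (-1.49 ± 0.26) among others. Their median was -0.82, their mean 0.11 and their adjusted p 0.506, and the median turned to 0.04 with the deposited ratios. The 8 heat-shock genes of CtsR and HrcA had 3 higher and 1 lower (3 and 1 adjusted over the list alone, adjusted p = 0.229), the lower one being clpE (-0.78 ± 0.16). The higher ones were mcsB (0.71), clpP (0.66) and mcsA (0.54). Without replicate 2 they had 0.59, 0.78 and 0.41 and were no longer called, nor were clpP (0.55) and mcsA (0.66) without replicate 1. The cold shock list had 1 lower gene of 3, the cold shock protein gene cspC at -0.80 ± 0.31, with values of -0.72 and -0.89 in the replicates, each uncalled alone (1 adjusted over the list alone, adjusted p = 0.019; adjusted p = 0.411 with an estimated correlation). For the peroxide list (0 higher, 1 lower, and 0 and 1 adjusted over the list alone; adjusted p = 0.299) the median was 0.18 and the mean -0.04. In all, 154 genes were higher and 79 lower. The split was 119 and 137 with loess on all genes, 191 and 8 with the deposited ratios, 179 and 18 with mode centring and 187 and 32 with loess and mode centring.

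After heat the largest values were those of gsiB (8.52 ± 0.49, 367-fold), mmgE (7.61 ± 0.28), ydaS (7.15 ± 0.34), yflT (6.44 ± 0.25), gspA (6.41 ± 0.40) and the cardiolipin synthase gene ywiE (5.88 ± 0.75). In the sigB operon, rsbX reached 5.63 ± 0.29, sigB 5.12 ± 0.26, rsbW 2.78 ± 0.19 and rsbV 2.67 ± 0.17. The gene rsbU, a phosphatase gene upstream, was called at 0.63 ± 0.18, and at 0.46 without replicate 1 was not. BSM29 was not detected for yqhQ (at least 26.2-fold higher, adjusted p = 3.13e-10) and yfhK (at least 13-fold, 2.18e-13). Lower in wild type were nap (-3.59 ± 0.39), opuBA (-1.14 ± 0.26), yisP (-1.04 ± 0.20) and ysdB (-1.01 ± 0.22), and the formate dehydrogenase-like gene yrhE (-1.14 ± 0.33), whose replicates of -1.02 and -1.25 were uncalled alone.

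Of the core SigB list, 73 of 101 genes were higher after heat and 2 lower (76 and 3 adjusted over the list alone, adjusted p = 8.51e-17). All 5 sigB operon genes were higher (5 adjusted over the list alone, adjusted p = 1.03e-15; adjusted p = 0.0567 with an estimated correlation). Among the 8 CtsR and HrcA genes no strain difference passed the test after heat: limma called 0, also at an unadjusted p under 0.05 (0 adjusted over the list alone, adjusted p = 0.341), with clpC at 0.09 ± 0.22, dnaK at 0.30 ± 0.27 and ctsR at 0.26 ± 0.24. In the osmoprotectant list 3 were higher and 3 lower (3 and 3 adjusted over the list alone), with a median of -0.14 and a mean of 0.36. Its fry test was positive (adjusted p = 0.00748), while camera pointed down (adjusted p = 0.694). The median turned to 0.18 with mode centring. Over all genes 130 were higher and 20 lower, or 102 and 93 with loess on all genes.

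Salt stress gave the largest mean sigB value of the 6 stresses, 6.45 ± 0.26 (87.2-fold), with rsbX at 6.49 ± 0.29, rsbV at 4.43 ± 0.17 and rsbW at 4.39 ± 0.19. Above it stood gsiB (8.36 ± 0.49), mmgE (7.06 ± 0.28), the universal stress protein gene nhaX (6.89 ± 0.29) and ydaS (6.61 ± 0.34), and yqgZ was at least 92.2-fold higher with a saturated wild-type signal (adjusted p = 2.28e-18). With BSM29 not detected, yqhQ was at least 32.6-fold higher (1.73e-11) and spoIIQ at least 4.93-fold (4.03e-11). The ribosomal protein L25-like gene ctc reached 3.89 ± 0.25, and the ribosome hibernation gene yvyD 1.47 ± 0.27. For ywiE the replicates lay at -0.17 and 6.41, so that its mean of 3.12 ± 0.75 was not called. Lower in wild type were nap (-3.52 ± 0.39) and opuAA (-1.61 ± 0.26, and -0.73 without replicate 1). Replicate 2 alone no longer called opuBA (-1.42 ± 0.26, alone -0.44), the homoserine dehydrogenase gene hom (-1.36 ± 0.25, alone -0.61) or csbC (-1.11 ± 0.26, alone -0.36).

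The core SigB list had 76 of 101 genes higher after salt and 4 lower (77 and 4 adjusted over the list alone, adjusted p = 2.71e-18). For the sigB operon 4 of 5 were higher (4 adjusted over the list alone, adjusted p = 1.2e-17; adjusted p = 0.0914 with an estimated correlation). Of the CtsR and HrcA genes, 5 of 8 were higher and 0 lower (5 and 0 adjusted over the list alone, adjusted p = 0.00174; adjusted p = 0.950 with an estimated correlation), the repressor gene ctsR at 1.16 ± 0.24 (0.74 without replicate 2), the protease genes clpP at 0.98 ± 0.23 and clpC at 0.83 ± 0.22, mcsA at 1.01 ± 0.22 and mcsB at 0.97 ± 0.23. Without replicate 2, clpC, mcsA and mcsB were no longer called (0.57, 0.69 and 0.60). The proline transporter gene opuE (4.23 ± 0.21) and opuBD (4.12 ± 0.30) were higher and 3 other osmoprotectant genes lower (2 and 3 adjusted over the list alone). The median of this list was -0.31 and its mean 0.28. Its fry test was positive (adjusted p = 0.0373), while camera pointed down (adjusted p = 0.416). The 3 cold shock genes had 0 calls in limma (1 at an unadjusted p under 0.05, 0 adjusted over the list alone) and shifted down on balance (adjusted p = 0.0279; adjusted p = 0.369 with an estimated correlation), with a median of -0.38 that turned to 0.19 with the deposited ratios. Over all genes 140 were higher and 40 lower. The split was 114 and 114 with loess on all genes, 162 and 2 with the deposited ratios, 145 and 5 with mode centring and 157 and 15 with loess and mode centring.

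Hydrogen peroxide gave smaller differences. The largest values were those of rsbX (4.88 ± 0.29), mmgE (4.53 ± 0.28), yqgZ (4.45 ± 0.23), sigB (4.14 ± 0.26, 17.6-fold) and yhdN (3.37 ± 0.16), with ywiE at 3.00 ± 0.75 (1.97 without replicate 1, uncalled). With BSM29 not detected, gsiB was at least 21.1-fold higher (adjusted p = 2.67e-09), ydaS at least 14-fold (4.29e-11), gspA at least 6.83-fold (8.02e-08), yfhK at least 4.59-fold (2.67e-09) and katE at least 3.96-fold (2.31e-06). The genes known to answer peroxide without SigB did not pass the test after peroxide, the vegetative catalase gene katA at -0.12 ± 0.54, mrgA at -0.15 ± 0.23 and the peroxiredoxin gene ahpC within a list with 0 calls in limma (0 at an unadjusted p under 0.05, 0 adjusted over the list alone, adjusted p = 0.809). In the change from 0 min this list also had 0 calls but shifted down on balance, with a median of -0.53. Its adjusted p there was 0.0277 with fry and 0.0826 with camera and an estimated correlation. Genes lower in wild type were nap (-4.27 ± 0.39) and the sporulation regulator gene spoIIID (-0.67 ± 0.22), uncalled in either replicate alone (-0.81 and -0.53).

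Of the core SigB list 46 of 101 were higher after peroxide and 0 lower (53 and 0 adjusted over the list alone, adjusted p = 3.46e-10). The sigB operon had 4 of 5 higher (4 adjusted over the list alone, adjusted p = 2.07e-12). In the osmoprotectant list 3 were higher and 0 lower (3 and 0 adjusted over the list alone, adjusted p = 0.0508). In all, 62 genes were higher and 2 lower, with 86 genes at an unadjusted p under 0.05. Without replicate 1 the total of 64 genes fell to 39.

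After glucose limitation the largest values were those of gsiB (8.19 ± 0.49, 293-fold), mmgE (6.81 ± 0.28), nhaX (6.79 ± 0.29), ydaS (6.59 ± 0.34), yflT (6.30 ± 0.25), ykzA (5.87 ± 0.28) and gspA (5.36 ± 0.40). In the sigB operon rsbX stood at 4.36 ± 0.29, sigB at 4.19 ± 0.26, rsbV at 3.81 ± 0.17 and rsbW at 3.64 ± 0.19. On the lower side stood nap (-2.78 ± 0.39), the Clp ATPase gene clpE (-1.14 ± 0.16) and dps (-0.94 ± 0.19). Uncalled in either replicate alone were the ferrichrome uptake gene fhuD (-1.07 ± 0.36, replicates -0.89 and -1.25) and the chaperone genes dnaK (-0.91 ± 0.27, replicates -1.01 and -0.80) and groEL (-0.74 ± 0.29, replicates -0.95 and -0.52).

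For the core SigB list 69 of 101 were higher after glucose limitation and 2 lower (71 and 2 adjusted over the list alone, adjusted p = 1.89e-15), and 4 of 5 operon genes were higher (4 adjusted over the list alone, adjusted p = 1.15e-15). Of the CtsR and HrcA genes 0 were higher and 3 lower (0 and 3 adjusted over the list alone, adjusted p = 0.0392; adjusted p = 0.369 with an estimated correlation), namely clpE, dnaK and groEL. The yce genes had 2 lower of 6 (3 adjusted over the list alone, adjusted p = 0.0114; adjusted p = 0.369 with an estimated correlation), yceC at -0.46 ± 0.17 and yceH at -0.68 ± 0.20, both uncalled in either replicate alone (replicates of yceC -0.60 and -0.32, of yceH -0.63 and -0.73). Osmoprotectant genes had 2 higher and 0 lower (2 and 0 adjusted over the list alone), with a median of -0.07 and a mean of 0.40. Their fry test was positive (adjusted p = 0.019), while camera pointed down (adjusted p = 0.845). The median turned to 0.20 with mode centring. In all, 104 genes were higher and 15 lower. With the deposited ratios 64 were higher and 119 lower, 183 together.

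Oxygen limitation gave gsiB at 6.07 ± 0.49 (67.2-fold), rsbX at 5.12 ± 0.29, mmgE at 5.06 ± 0.28, ydaS at 4.90 ± 0.34, sigB at 4.80 ± 0.26, ykzA at 4.71 ± 0.28 and yqgZ at 4.70 ± 0.23. BSM29 was not detected for yqhQ, which was at least 12.8-fold higher (adjusted p = 1.74e-08). Lower in wild type were nap (-3.91 ± 0.39), feuA (-3.18 ± 0.31, and -1.98 without replicate 1) and dhbA (-3.09 ± 0.44, and -1.38 without replicate 1). The iron uptake genes were already lower at 0 min of this series, dhbA at -6.02 and -5.26 and feuA at -4.47 and -3.20. Of further lower genes, a pair rested on replicate 1, fhuD (-1.68 ± 0.36, -0.34 without it) and the choline uptake gene opuBC (-1.27 ± 0.36, -0.69 without it).

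Of the core SigB list 60 of 101 were higher after oxygen limitation and 3 lower (62 and 3 adjusted over the list alone, adjusted p = 3.42e-13), and the operon had 4 of 5 higher (4 adjusted over the list alone, adjusted p = 1.11e-14). The CtsR and HrcA genes had 4 higher of 8 and 0 lower (5 and 0 adjusted over the list alone, adjusted p = 0.00135; adjusted p = 0.691 with an estimated correlation). These 4 were clpC (0.89 ± 0.22), groEL (0.84 ± 0.29), mcsA (0.82 ± 0.22) and mcsB (0.80 ± 0.23), all uncalled without replicate 1 (0.41, 0.02, 0.36 and 0.36). The cold shock list had 2 of 3 lower (2 adjusted over the list alone, adjusted p = 0.00811; adjusted p = 0.303 with an estimated correlation), the fatty acid desaturase gene des (-1.04 ± 0.27) and cspC (-0.79 ± 0.31), which without replicate 1 had -0.55 and -0.32, uncalled. Osmoprotectant genes had 2 higher and 1 lower (2 and 1 adjusted over the list alone), a median of 0.03 that turned to -0.21 with mode centring, and a positive test (adjusted p = 0.00217; adjusted p = 0.950 with an estimated correlation). Over all genes 90 were higher and 26 lower, 81 and 58 with loess on all genes, and the total of 116 fell to 77 without replicate 1. At 0 min of this series the fit of single times already called 36 genes higher and 41 lower. In the other series at 0 min it called 3 to 16 higher and 1 to 6 lower. The strains in this series thus differed in many genes before oxygen was limited.

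Growth at 15 °C asks for the strain difference in the cold. At OD 0.9 the largest values were those of gsiB (7.59 ± 0.24, SE, n = 8 arrays), mmgE (6.88 ± 0.14), ywiE (6.40 ± 0.38), rsbX (5.50 ± 0.14), sigB (4.91 ± 0.13), yvgO (4.79 ± 0.18), yqhQ (4.68), yqgZ (4.55 ± 0.12) and bioA, a biotin synthesis gene (4.41 ± 0.23). The gene gspA, not detected in BSM29, was at least 26.6-fold higher (adjusted p = 6.2e-19). Smaller values went to yvyD (0.94 ± 0.13) and to the superoxide dismutase gene sodA (0.82 ± 0.14). Lower in wild type were nap (-4.04 ± 0.20), ytiA (-1.90 ± 0.56), katA (-1.43 ± 0.27), spsA (-1.34 ± 0.14) and ywdL (-0.99 ± 0.17), the last pair known from spore coats.

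In the cold 72 of 101 core SigB genes were higher and 4 lower (73 and 4 adjusted over the list alone, adjusted p = 3.68e-19), and all 5 operon genes were higher (5 adjusted over the list alone, adjusted p = 4.77e-21). The peroxide list had 1 of 5 higher and 2 lower (1 and 2 adjusted over the list alone, adjusted p = 0.019; adjusted p = 0.369 with an estimated correlation), namely sodA against katA and mrgA (-0.40 ± 0.11). At OD 1.0 its test was positive (2 higher and 0 lower, 2 and 1 adjusted over the list alone, adjusted p = 1.67e-05; adjusted p = 0.925 with an estimated correlation), and its median of 0.22 turned to -0.03 with the deposited ratios. Osmoprotectant genes had 3 higher and 2 lower (3 and 2 adjusted over the list alone). Their fry test was positive (adjusted p = 0.000102), while camera pointed down (adjusted p = 0.845). Their median of 0.12 turned to -0.30 with the deposited ratios. The cold shock list had 0 calls in limma (0 at an unadjusted p under 0.05, 0 adjusted over the list alone, adjusted p = 0.599), with des at -0.09 ± 0.13, cspB at 0.06 ± 0.12 and cspC at -0.17 ± 0.15. Over all genes 138 were higher and 65 lower at OD 0.9, 117 and 101 with loess on all genes, and 81 and 160 with the deposited ratios. The arrays titled OD 1.0, for which other labels give 0.9, had 118 higher and 30 lower (n = 2), 102 and 67 with loess on all genes, and 134 and 3 with mode centring.

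The remaining 3 lists had only 2 measured genes each and were not tested. In the oxygen and nitrate list, lctP, a lactate permease gene, was called after heat (1.12 ± 0.33, and 0.99 without replicate 2, uncalled; 1 adjusted over the list alone), and the lactate dehydrogenase gene ldh was not called after any stress. In the carbon list the aconitase gene citB was lower after ethanol (-0.92 ± 0.26, and -0.83 without replicate 2, uncalled; 1 adjusted over the list alone) and higher at 15 °C (0.54 ± 0.13; 1 adjusted over the list alone). Both housekeeping genes, tufA (0.69 ± 0.12) and eno (0.55 ± 0.10), were higher at 15 °C (2 adjusted over the list alone), eno turning to -0.15 with the deposited ratios.

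Comparing the stresses asks which SigB genes answer alike. Over the 6 stresses 52 genes were higher in wild type in all 6, 96 in at least 4 and 186 in at least 1, while nap was the 1 gene lower in all 6. Of the 52 genes, 40 are on the SigB lists, and 12 are not: mmgE, spoIIQ, opuBD, bioA, ycbP, ywjA, ywjB, ydgC, yshC, ywtA, yfhO and yvaA. Outside that set, 17 list genes were higher in no stress, csbB, csbC, csbX, yceD and ydbD among them. The strain difference varied among the stresses in 197 of 350 genes by limma's F-test, 87 of them among the 102 list genes.

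**Figure D2:**
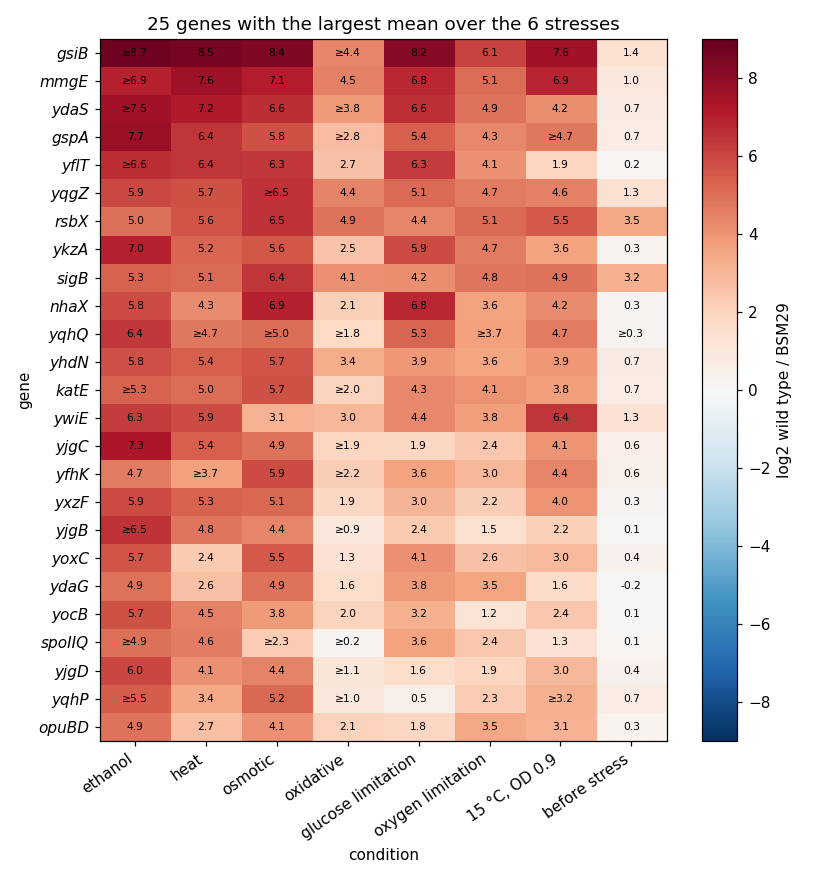
Log2 of wild type over BSM29 (colour and printed value) for the 25 genes with the largest mean over the 6 stresses (vertical axis), by condition (horizontal axis); a value after ≥ is a bound, for genes not detected in BSM29 or saturated in wild type. The gene gsiB has 8.52 after heat and 1.37 before stress.

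In contrasts between stresses, larger means a more positive log2 value, so a less negative value also counts as larger. Ethanol gave the larger value in 126 genes and peroxide in 39 of the 165 that differed between these stresses. The median difference over the SigB lists was 1.62. Between salt and peroxide it was 1.79, with 114 genes larger after salt and 17 after peroxide. Peroxide and oxygen limitation had the fewest differing genes, 33 (10 larger after peroxide, 23 after oxygen limitation), with a list-median difference of -0.36. Ethanol and salt differed in 101 genes, 60 larger after ethanol and 41 after salt, with the smallest list-median difference, 0.14. The list medians after each stress were 2.92 for ethanol, 1.83 for heat, 2.56 for salt, 0.64 for peroxide, 1.41 for glucose and 1.21 for oxygen limitation. With genes known only by a bound set to it, they were 2.70, 1.82, 2.54, 0.62, 1.41 and 1.05.

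A few genes were called higher in wild type in 1 stress alone. After ethanol these numbered 14, with ytiA (5.47), ywlB (1.65 ± 0.15) and ygxA (1.42 ± 0.18) the largest. For ytiA the mean of the other 5 stresses was 1.31, and replicate 1 had 4.47 after glucose limitation and 3.72 after salt, where the means were not called. Salt had 11, led by ywsB (1.57 ± 0.20), yvyD (1.47 ± 0.27) and ysnF (1.47 ± 0.27), heat 6, oxygen limitation 5 and glucose limitation 3. Against the mean of the other 5 stresses, limma tested the signed log2 value over all 350 genes. It called 114 genes more positive and 45 more negative after ethanol, 42 and 10 after heat and 77 and 16 after salt. The counts were 13 and 111 after peroxide, 16 and 48 after glucose and 20 and 86 after oxygen limitation. Among single-stress genes lctP (heat), pdhA (glucose) and mdh (oxygen) were not called in this contrast. The DNA glycosylase gene yxlJ was 1.60 ± 0.24 (0.85 without replicate 2) after oxygen limitation against a mean of -0.34 elsewhere.

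In a fit that does not pair the replicates, the change from 0 min takes away what differed at 0 min. By this measure sigB rose by 2.20 ± 0.37 after ethanol (adjusted p = 1.24e-05). The core SigB list had 73 of 101 genes with a rise after ethanol (74 adjusted over the list alone), 66 after heat (68 adjusted over the list alone), 70 after salt (72 adjusted over the list alone), 31 after peroxide (35 adjusted over the list alone), 62 after glucose (63 adjusted over the list alone) and 60 after oxygen limitation (62 adjusted over the list alone). The mannose gene manP went the other way, by -3.49 ± 0.35 after glucose and -4.05 ± 0.35 after oxygen limitation. Without replicate 1 these were -3.01 and -2.74, and without replicate 2 -3.97 and -5.37. For yvgW the difference deepened by -2.10 ± 0.48 after ethanol, and dhbA moved by 2.55 ± 0.62 toward 0 in the oxygen series (3.88 without replicate 1, and 1.21, uncalled, without replicate 2). Over all genes, rises and falls of the signed value numbered 134 and 43 after ethanol and 103 and 1 after heat. They numbered 122 and 12 after salt and 39 and 0 after peroxide (limma, 59 genes at an unadjusted p under 0.05). Glucose gave 95 and 15 and oxygen limitation 105 and 28. With loess on all genes they were 111 and 121, 93 and 52, 97 and 65 and, for oxygen, 92 and 54. With the deposited ratios ethanol gave 119 and 7 and oxygen 128 and 2, and mode centring gave 153 and 6 after ethanol, or 157 and 8 with loess before it. Leaving out replicate 1 gave 16 genes for peroxide, 60 for glucose and 66 for oxygen, and leaving out replicate 2 gave 11 for peroxide. With replicate number as a block the totals were 214 after ethanol, 125 after heat, 157 after salt, 50 after peroxide, 129 after glucose and 156 after oxygen limitation.

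The time courses ask when the strain difference was largest. The median of the SigB-list genes rose from 0.05 at 0 min to 3.44 ± 0.33 (SD, n = 2) at 5 min of ethanol and lay at 1.88 ± 0.01 at 20 min. In the heat series it was 2.44 ± 0.60 at 5 min and 0.94 ± 0.04 at 20 min, and with salt it was 2.52 ± 0.26 at 5 min, 2.71 ± 0.10 at 10 min and 2.13 ± 0.32 at 20 min. Peroxide peaked at 0.71 ± 0.03 at 5 min. Glucose limitation climbed from 0.90 ± 0.01 at 15 min to 1.61 ± 0.04 at 60 min and lay at 1.14 ± 0.11 at 90 min, and oxygen limitation reached 1.31 ± 0.38 at 45 min and 0.57 ± 0.33 at 90 min. Taken with its sign, the log2 value fell between 5 and 20 min in 93 genes with ethanol and rose in 20. It fell in 76 with heat. With salt it fell in 13 and rose in 3, and the median change of the list genes was 0.04. With peroxide limma called 0 genes between these times (15 at an unadjusted p under 0.05).

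**Figure D3:**
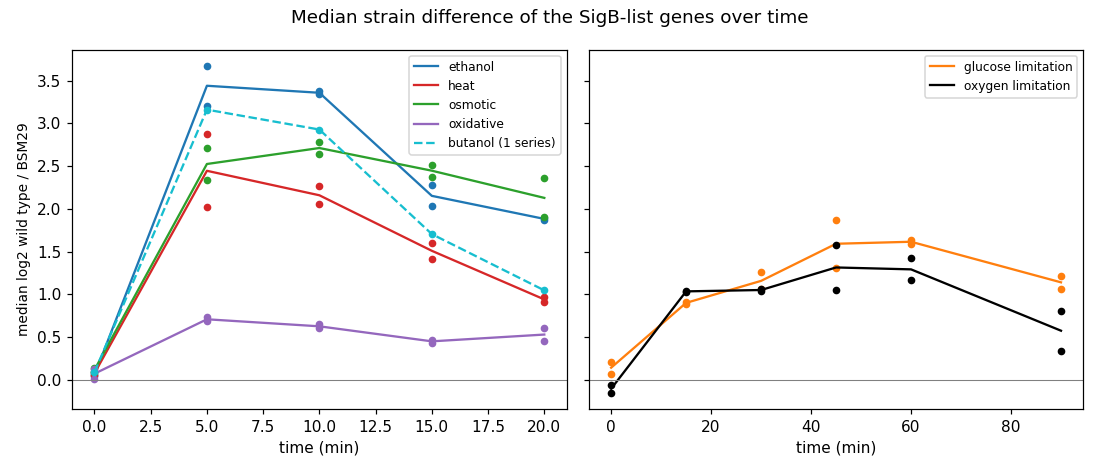
Median log2 of wild type over BSM29 over the SigB-list genes (vertical axis) against minutes of stress (horizontal axis), with 1 point per biological replicate and a line through their mean; butanol has 1 culture series. Ethanol stands highest with 3.44 at 5 min, and peroxide reaches 0.71.

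Ethanol and butanol are alcohols of different chain length, given at 4% and 1% by volume, so that their doses differ. Butanol has n = 1 and was not tested. The list median ran 3.44, 3.36, 2.15 and 1.88 at 5, 10, 15 and 20 min of ethanol against 3.16, 2.93, 1.70 and 1.05 with butanol. Across genes, which are not independent, the profiles correlated at r = 0.94 at 5 min and 0.88 at 20 min. The sigB value was 5.32 with ethanol and 4.79 with butanol, and rsbX had 4.99 and 5.78. All 4 butanol values lay outside the range of the 8 ethanol values in 20 genes, 9 higher and 11 lower with butanol; chance would give 0.404% of genes if all values were exchangeable, which times of 1 culture are not. Among these, ytiA had 5.47 with ethanol and -0.08 with butanol and yvgW -3.97 and -0.02, but at 0 min the ethanol cultures already stood at 3.95 and 6.38 for ytiA and at -1.95 and -1.80 for yvgW. Of the others, yoxC had 5.67 and 3.34, ykzA 6.96 and 4.80 and the ribosome maturation gene rbfA 3.13 and 0.94.

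Within each strain the signals show what each one induced by itself. In wild type the SigB-list median rose by 3.04 after ethanol, 1.81 after heat, 2.56 after salt, 0.64 after peroxide, 1.71 after glucose and 0.88 after oxygen limitation. In BSM29 it was 0.24, -0.09, 0.01, 0.15, 0.41 and -0.22. After ethanol clpC rose by 4.22 ± 0.77 in BSM29 and by 4.80 ± 0.76 in wild type, mcsB by 4.13 ± 0.56 and 5.32 ± 0.49, and yvyD by 3.43 ± 0.67 and 3.54 ± 0.61. Heat raised the chaperonin gene groEL by 2.46 ± 0.44 in BSM29 and 2.61 ± 0.31 in wild type, clpP by 2.34 ± 0.38 and 2.47 ± 0.39, and the biotin gene bioW by 4.50 ± 0.70 and 3.96 ± 0.42. Salt raised yhaT (2.99 ± 0.37), opuCA (2.52 ± 0.41) and yceG (2.36 ± 0.34) in BSM29, and 3.02 ± 0.25, 2.43 ± 0.34 and 2.27 ± 0.27 in wild type. The 6 genes that peroxide raised in BSM29 were dhbA (3.87 ± 0.80), katA (3.76 ± 0.72), mrgA (3.05 ± 0.46), the SOS repressor gene lexA (2.01 ± 0.34), yqhA (1.15 ± 0.30) and yxzF (1.05 ± 0.26), all of them also up in wild type.

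Glucose limitation raised yqhP by 5.42 ± 0.49 in BSM29 and 3.49 ± 0.74 in wild type, and manP by 4.32 ± 0.47 and 0.83 ± 0.30. Oxygen limitation raised ldh by 7.84 ± 0.34 in BSM29 and 6.81 ± 0.32 in wild type, and ydbC by 5.76 ± 0.53 and 5.62 ± 0.53. In wild type the genes up and down numbered 168 and 78 after ethanol, 136 and 34 after heat, 136 and 46 after salt, 61 and 7 after peroxide, 145 and 59 after glucose and 95 and 46 after oxygen limitation. In BSM29 they numbered 59 and 41, 25 and 13, 31 and 25, 6 and 4, 78 and 47, and 14 and 12, of which 55, 24, 28, 6, 67 and 12 were up in both strains. Totals in BSM29 after heat, salt and oxygen limitation were 38, 56 and 26, or 79, 90 and 65 with quantile-scaled signals. With replicate number as a block, BSM29 had 122, 64, 85, 17, 177 and 50 changed genes in the 6 stresses, and wild type 260, 208, 203, 93, 233 and 169.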

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

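The tests of ytiA, yvgW, dhbA and feuA at 0 min and from 0 min, of mode centring, of nap before and from 0 min and of sign changes of whole series were chosen after the results were seen; the dye and saturation tests and the sign changes at 15 °C were not.

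At 15 °C and OD 0.9, 1 array stood apart for gsiB with 9.05 (next highest 7.88) and 1 for rsbV with 2.89 (next lowest 3.40), out of 26 values tested; chance flags about 1 in 20 groups. For genes called in 1 stress alone, the difference from the mean of the other 5 stresses was taken with an adjusted p over all 350 genes; since the genes were picked for this pattern, it is no independent evidence. The 3 genes lctP, pdhA and mdh did not pass. With ethanol this difference was 1.52 for ygxA, 4.17 for ytiA and 1.63 for ywlB. With heat it was 0.62 for rsbU and 0.81 for ycdG. With salt it was 1.44 for ysnF, 1.40 for yvyD and 1.66 for ywsB. With glucose limitation it was 0.68 for gerPA and 0.82 for sspE, and with oxygen limitation 1.11 for groEL and 1.93 for yxlJ. The calls of rsbU (0.46) and ycdG (0.27) ended without replicate 1 of heat, that of groEL (0.02) without replicate 1 of oxygen limitation, and those of gerPA and sspE without either replicate of glucose limitation.

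The genes ytiA and yvgW stood apart in the ethanol series and dhbA and feuA in the oxygen series, 4 genes chosen after their values were seen (fhuD at 0 min of the latter was uneven, -2.71 and -0.82), and ytiA also in replicate 1 of glucose limitation (6.38 at 0 min) and of salt (3.88). A response to ethanol as the whole difference is argued against for ytiA, whose lower value at 0 min was already 3.95 and whose change was 0.31 with a standard error of 1.60, while yvgW did deepen, by -2.10 ± 0.48. In the oxygen series dhbA moved toward 0 by 2.55 (1.21 and 3.88 in replicates 1 and 2) and feuA by 0.65 ± 0.44 (0.08 and 1.22), mainly in replicate 2, against a fall that oxygen limitation would have to bring. A dye effect is argued against by the swapped arrays, where ytiA had a mean of 4.54 and the highest mean of yvgW, dhbA and feuA was -2.25. A difference between the strains' cultures before the stress remains a candidate explanation, with the highest of the 6 values of yvgW, dhbA and feuA at 0 min being -1.80, and for yvgW an ethanol response on top of it stays open.

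After ethanol 79 genes were lower in wild type. With the loess kept and arrays centred on the mode of the genes outside the lists, 40.5% of them stayed lower. Without the loess, 74.7% stayed lower with median and 22.8% with mode centring. Mode centring raised the median of all genes by 0.35 log2 with the loess and 0.46 without it, so fewer lower calls follow from the shift itself. Many of these calls thus depend on the centring. These shares cannot tell which centring is right, nor whether genes higher in wild type among those used for it account for the calls. Saturated wild-type signals are argued against, with 0% of the 79 genes saturated on any array after ethanol. Which share reflects lower expression in wild type stays open.

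The esterase gene nap was lower in wild type before stress, after each of the 6 stresses and at 15 °C. Swapped arrays gave it a mean of -3.86, which argues against a dye effect, and its value before stress was -4.64, which argues against a response to the stresses as the whole difference. The difference shrank by 1.94 ± 0.55 after glucose limitation and 1.60 ± 0.55 after salt, so a part may go with these stresses, though the calls ended without replicate 2 of glucose limitation (1.63) and replicate 1 of salt (1.19). A difference between the strains besides SigB stays open and was not tested.

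Sign changes asked whether counts of called genes exceed chance. At 15 °C and OD 0.9 the real signs gave 189 genes in a fit of these arrays alone, where the main fit had called 203. The highest of the other sign changes gave 82, so that 1 of 100, the real one, gave as many. Chance is excluded only if the 8 arrays are independent. For ytiA some neighbours were alike, with -3.05 and -3.04 in replicates 5 and 6 and -0.45 and -0.89 in replicates 7 and 8. All 8 had BSM29 in Cy3, and sign changes cannot test a bias they share. Before stress the signs of whole series were changed, since cultures of a series can resemble each other; changing single arrays, as first planned, gave at most 18 genes in the other sign changes. The real signs gave 25 genes in a fit of these arrays alone, where the main fit had called 51. The highest other sign change gave 24, so that 1 of 32, the real one, gave as many. This is the smallest share that 6 series allow. With a margin of 1 gene, the test does not set the count before stress clearly apart from chance.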

How the results depend on the processing

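Mode centring with and without loess, the floor of 25, the offset of 50, all spots kept and centred deposited ratios were chosen after the data were seen. Of 8122 values of named genes under the alternatives, 7651 (94.2%) kept their call or stayed uncalled, 272 lost the call and 180 gained one. A further 19 reversed direction with a call in at least 1 of the 2 settings. Values uncalled in both settings counted as kept whatever their direction, so reversals among them are not counted. Of the counts under alternatives that leave out no replicate or series, 213 stayed within 1.5 times and 20 did not. The block by replicate number raised every count of changes from 0 min, by more than 1.5 times only for those below. Where 1 replicate is left out, the other is assumed to vary like the remaining groups. Signals near the floor limit what can be seen in BSM29, where as few as 207 genes were detected on an array. Not run were centring on housekeeping genes (2 of 23 on the array), no background correction (signals come subtracted) and a scan batch (none is given). The cause of the changes below was not tested, except that reversals with the deposited ratios are set beside the centred ratios.

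Before stress 51 genes were called, 114 without dye correction, 163 with deposited ratios and 30 with mode centring. With deposited ratios glucose limitation gave 183 and its change 72. In BSM29, quantile-scaled signals gave 79 changed genes after heat, 90 after salt and 65 after oxygen limitation, and the replicate block 64, 85, 17 (peroxide) and 50 (oxygen). With camera 1 list passed after ethanol, heat, salt and before stress, and 2 after peroxide (unchanged), glucose, oxygen and at 15 °C (both densities). Camera puts another question than fry, so these counts are no repeat of the same test. Leaving out 1 replicate gave 39 to 43 genes after peroxide and 11 to 16 for its change, 60 to 81 for the change with glucose, 77 to 129 after oxygen limitation and 66 to 127 for its change. Leaving out 1 series, dhbA before stress ran from -1.19 to 0.15 and feuA from -0.68 to 0.19.

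With loess on all genes sodA after ethanol turned to -0.75 and ahpC after heat to -0.0694. With deposited ratios, ahpC after salt turned to 0.11. After glucose limitation they turned citB to -0.82, citZ to -0.92, cspC to -0.83, gerPA to -0.13, pdhA to -0.0356 and tufA to -0.94. At 15 °C they turned clpC to -0.55, clpE to -0.43, cspB to -0.51, dps to -0.28, eno to -0.15, opuBC to -0.0335, yceD to -0.38 and yceE to -0.43. These uncentred ratios shifted the median of all genes by -0.66 after glucose limitation, -0.42 at 15 °C (OD 0.9) and 0.62 after salt. Centred deposited ratios reversed no named gene, so these 15 reversals go with the offset of the deposited columns.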

Other observations

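All observations here were chosen after the values were seen, and no hypothesis was tested on them.

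The genes named here were picked among those that fell in both strains and stand for no gene group. Others rose in both strains, among them bioW after heat and ldh after oxygen limitation. After ethanol the purine synthesis gene purK changed by -5.14 ± 0.39 in wild type and -4.53 ± 0.45 in BSM29 (SE, n = 2), the sulfate assimilation gene sat by -4.60 ± 0.34 and -3.67 ± 0.35, and the ribosomal protein gene rplJ by -4.11 ± 0.33 and -4.10 ± 0.42. Glucose limitation changed the NAD synthesis gene nadC by -5.85 ± 0.32 and -5.10 ± 0.36, bioB by -5.11 ± 0.29 and -4.58 ± 0.38, and pdhA by -3.06 ± 0.28 and -4.38 ± 0.30. After heat the cold shock gene cspB changed by -3.16 ± 0.31 in wild type and -2.59 ± 0.33 in BSM29. Oxygen limitation changed des by -2.55 ± 0.38 and -2.78 ± 0.58.

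In 2 sets of genes with related names, values lay apart, with no test between them. After heat mmgE stood at 7.61 ± 0.28, while mmgB (-0.42 ± 0.17) and mmgD (-0.27 ± 0.22) were not called. The biotin gene bioA was higher in wild type at 15 °C (4.41 ± 0.23), where bioW was lower (-0.94 ± 0.16) and bioB (-0.05 ± 0.11) was not called.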
